A study of Rattus with 6 samples.

How the data were processed

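The study measured circular RNA (circRNA, RNA closed into a ring by back-splicing) in heart muscle of 6 male Sprague-Dawley rats on 6 microarrays. Per the labels, 3 rats had the left anterior descending coronary artery tied for 40 min and then released for 2 h, and in 3 control rats the thread was passed but not tied. The series design text describes 6 separate animals, so each array was treated as 1 biological replicate. Per the labels' protocols, total RNA was extracted with Trizol and copied with random primers into Cy3-labelled cRNA by the array maker's labelling protocol. Whether linear RNA was removed before labelling is not given in the sources used here.

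The deposited scanner tables hold spot intensity values on a linear scale, 1 table per array, made with Agilent Feature Extraction 11.0.1.1 by a 1-colour protocol, per the file headers. In those tables the processed intensity was background-subtracted and detrended within each array by that software, per the file headers, with no normalization between arrays. All 6 tables carry the same scan identifier, so the arrays came from 1 scan of 1 slide and no slide or scan batch could be tested. The 3 ischemia-reperfusion arrays and control replicate 1 lay in the first row of the slide, and control replicates 2 and 3 in the second row. A deposited series table gives log2 values for the same circRNA probes, and how the authors made it is not stated. Its columns had nearly equal distributions, with medians of 5.69, 5.68 and 5.69 for ischemia-reperfusion replicates 1 to 3 and 5.68, 5.68 and 5.68 for control replicates 1 to 3. Each column followed the log2 median spot intensity of its own array, with a rank correlation over probes of at least 0.998, against at most 0.980 with another array. The exact scaling of that deposited log2 table stays unknown.

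Each array held 14145 circRNA probes with 1 spot each, 62 probes for mRNA with 10 spots each, 20 custom probes without a name, and 536 control spots. The header names the rn4 rat build for the design. The tables pair circRNA probes with an ID only. No table of host genes or circRNA classes was used here, so the planned tests of host gene lists, circRNA classes and circRNAs of one host were not run, and at most 2 circRNA IDs are printed per direction. Of the 62 mRNA probes, 39 carried an accession found in the RefSeq gene table of assembly GRCr8, which named 38 genes. That table served for names only. The mRNA probes became a comparison only after the files had been examined.

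Processed intensities were taken to log2, and the 75th percentile of the circRNA probes of the same array was subtracted. All normalized values below are on that scale, where 0 is the 75th percentile. Control spots and spots flagged as outliers were left out, saturated spots would have been kept, and spots of one probe were averaged. A probe was called detected when the software marked it as well above background, and an mRNA probe when over 50% of its spots were. Probes detected on all 3 arrays of at least 1 group were tested. The 2 groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, on all 6 arrays without covariates, and p-values were adjusted by Benjamini-Hochberg over the circRNA probes tested or over the mRNA probes tested. A call required an adjusted p under 0.05. A second count, of circRNAs at 1.5-fold or more with an unadjusted p under 0.05, follows a rule common for circRNA arrays. For a probe below background on every array of a group, the fold was given as a lower bound, against the higher of its own signal and the lowest detected signal on each array. Numbers of detected probes were compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9.

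The rule for named circRNAs was fixed before the data were examined, as were the groups, the tests and the first set of other settings. It took the 10 largest rises and 10 largest falls among non-overlapping circRNAs past the adjusted threshold, filled up from non-overlapping circRNAs of at least 1.5-fold by smallest unadjusted p. All 20 came from the second step. Among mRNA probes, each probe matched to a gene and detected on all 6 arrays was named, a rule set after the files had been examined. The 15 gene lists, with 803 genes, were fixed beforehand as host gene lists. Only their members among the mRNA probes could be counted, and none reached the 5 members required for a test.

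The labels number the replicates 1 to 3 in both groups. Deviations from the group means correlated between same-numbered arrays of the 2 groups at r = 0.60, 0.29 and 0.19 across circRNA probes, which are not independent replicates. All 3 exceeded the limit of 0.1 set for treating the numbers as pairs, and in the brightest 25% of tested probes the values were 0.56, 0.20 and 0.34. With differently numbered arrays the highest values were -0.43, 0.21 and 0.09 for replicates 1 to 3. The value of 0.21 also exceeded the limit, so the limit alone does not single out same-numbered arrays. The pairing rests on these data, since the labels do not say what a number stands for. A fit with the replicate number as a block was therefore run beside the unblocked fit.

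The test was tried on simulated data with the means and spreads of 12960 circRNA probes and 200 changed probes in each of 20 runs. It recovered 50.6% of 2-fold changes and 98.0% of 4-fold changes at an adjusted p under 0.05, with 9 false calls per run. The simulated noise was independent between probes and arrays. Deviations shared by many probes of an array, as seen in these data, were not simulated, so these shares need not hold for the real arrays. The number of arrays limits the precision. Other settings fixed beforehand were quantile scaling, scaling to the median, the percentile over probes detected on all arrays, no filter on dim probes, only probes detected on all 6 arrays, the deposited log2 table, eBayes with trend and robust options, a plain two-sample test, the replicate block and leaving out each array. The planned normexp correction of mean spot intensity was not run because that column was not among those used here. Settings chosen after seeing the data were normexp with an offset of 50 on the median spot intensity, cyclic loess, array quality weights, the slide row as a block, the brightest 25% of circRNAs, another detection flag, and each mRNA probe taken relative to the 200 circRNA probes closest in mean signal.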

Results

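Expression of circRNAs was profiled in rat heart muscle after ischemia-reperfusion, in which blood flow is stopped and then restored. Hearts of 3 rats with 40 min of coronary occlusion and 2 h of reperfusion were compared with hearts of 3 rats that had the same surgery without occlusion. Of 14145 circRNA probes, 13606, 12369 and 13538 were detected above background on ischemia-reperfusion arrays 1 to 3, and 14051, 13304 and 12939 on control arrays 1 to 3. The number detected did not differ beyond the spread between animals, at 13171 ± 695 after ischemia-reperfusion and 13431 ± 567 in controls (SD, n = 3 each, exact permutation p = 0.7, smallest possible 0.1). The 75th percentile of circRNA signal was 85.2, 64.4 and 102 intensity units on the ischemia-reperfusion arrays and 94.9, 90.4 and 70.8 on the control arrays. Outlier flags removed 1, 1 and 2 circRNA spots from the ischemia-reperfusion arrays and 0, 2 and 1 from the control arrays, and no circRNA spot was saturated.

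The first comparison asked which circRNAs differed 2 h after reperfusion. No circRNA passed an adjusted p of 0.05 in limma among 12967 tested, where the smallest adjusted p was 0.428 and 1483 had an unadjusted p under 0.05. The 10 named circRNAs with higher values had log2 differences of 0.70 to 1.39, and 9 of the 10 with lower values had differences of -1.38 to -0.69. The other was below background on all 3 ischemia-reperfusion arrays and at least 1.45-fold lower. None of the 20 passed the test. ASCRPR010701 had a normalized log2 signal of 1.21 ± 0.24 after ischemia-reperfusion and 0.27 ± 0.16 in controls (SD, n = 3 each), a difference of 0.93 (SE 0.19, limma adjusted p = 0.428). ASCRPR002405 had 1.62 ± 0.24 against 0.73 ± 0.12 (SD, n = 3 each), a difference of 0.89 with the same limma adjusted p. The lowest unadjusted p belonged to ASCRPR001910, at -3.57 ± 0.06 after ischemia-reperfusion against -2.58 ± 0.08 in controls (SD, n = 3 each, limma adjusted p = 0.428). ASCRPR008444 had -4.0 ± 0.11 against -3.08 ± 0.15 (SD, n = 3 each, limma adjusted p = 0.428) and was above background on 2 of the 3 ischemia-reperfusion arrays. With normexp and 75th percentile scaling the 4 differences, in the order given, were 0.73, 0.71, -0.11 and -0.16, and they were 0.90, 0.86, -0.18 and -0.33 in the deposited log2 table, whose exact scaling is unknown. The normexp values include an added offset of 50 intensity units, which shrinks differences of dim probes such as the 2 lower ones by construction. In each of these 4 circRNAs all 3 values of one group lay outside the range of the other, as the rule for naming required.

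Chance alone would give 648 circRNAs with an unadjusted limma p under 0.05. Other splits of the 6 arrays into 3 and 3 gave 63 to 1820, and those with 1820 and 1721 exceeded the 1483 of the real split. Of the 1483 seen, 507 were higher and 976 lower after ischemia-reperfusion. The number depended on single arrays, at 681, 545 and 1429 without ischemia-reperfusion replicates 1 to 3 and 3557, 839 and 752 without control replicates 1 to 3. At 1.5-fold or more, 280 of these were higher and 443 lower, so that 61.3% were lower. The 3 values of one group lay entirely above or below those of the other for 2238 circRNAs, or 17.3%, where chance gives 10%. The median log2 difference of all tested circRNAs was -0.11, and it was -0.01 with quantile scaling, which gives the arrays 1 distribution by construction. Detection on every control array and on no ischemia-reperfusion array was seen for 2 circRNAs, which were at least 1.45-fold and 1.78-fold lower after ischemia-reperfusion (limma adjusted p = 0.428 for both). The opposite pattern was seen for 0 circRNAs.

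With the replicate number as a block, 1 circRNA was higher and 16 were lower past the adjusted threshold (smallest limma adjusted p = 0.0330, range over all alternatives 0.00985 to 0.737), and 380 and 808 reached 1.5-fold with an unadjusted p under 0.05. Array quality weights, which gave control replicate 2 a weight of 6.16 and control replicate 1 a weight of 0.207, placed 1444 circRNAs higher and 1930 lower past the adjusted threshold. Among circRNAs at 1.5-fold or more with an unadjusted p under 0.05, the share that was lower depended on the scaling. It was 28.7% with quantile scaling (517 higher, 208 lower), 29.1% with cyclic loess (572 and 235), 50.4% with scaling to the median (452 and 460), 40.8% with normexp (93 and 64), 4.23% with normexp and quantile scaling (136 and 6), and 8.8% in the deposited log2 table (228 and 22). The normexp offset of 50 intensity units keeps dim circRNAs from reaching 1.5-fold, so the normexp shares describe bright ones. Leaving out ischemia-reperfusion replicates 1, 2 or 3 gave 98 higher and 530 lower, 176 and 188, and 464 and 673. Leaving out control replicates 1, 2 or 3 gave 945 and 867, 157 and 539, and 96 and 458.

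The directions differed between dim and bright probes, in a way that turned round without control replicate 1. With the tested probes split at their median signal, 52 circRNAs were higher and 314 lower at 1.5-fold with an unadjusted p under 0.05 in the dimmer part, and 228 were higher and 129 lower in the brighter part. Without control replicate 1 there were 369 higher and 185 lower in the dimmer part and 576 and 682 in the brighter part. In the dimmer part the counts were 24 and 495, 54 and 109, and 71 and 370 without ischemia-reperfusion replicates 1 to 3, and 29 and 494, and 20 and 415 without control replicates 2 and 3. In the brighter part they were 74 and 35, 122 and 79, and 393 and 303, and then 128 and 45, and 76 and 43. In the dimmer part the majority also changed to higher with quantile scaling (215 and 150), cyclic loess (196 and 179) and array quality weights (404 and 230), and the deposited log2 table held 2 higher and 0 lower there. In the brighter part it changed to lower with array quality weights (495 and 711). It also did so with the slide row as a block, which by construction compares the ischemia-reperfusion arrays with control replicate 1 alone. In the dimmest 10% of tested circRNAs the median log2 difference was -0.32, and it was -0.07 without control replicate 1, whose dim probes were 0.87 above the mean of the other 5 arrays on the log2 scale. In the brightest 10% the median difference was -0.24, and -0.39 without control replicate 1. There the median signals were 2.60, 2.72 and 2.67 on ischemia-reperfusion arrays 1 to 3. They were 2.59, 2.92 and 2.95 on control arrays 1 to 3. Without control replicate 1, the ischemia-reperfusion arrays lay in the first row of the slide and the controls in the second. In every fit without that array, group and slide row therefore could not be told apart.

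**Figure D1:**
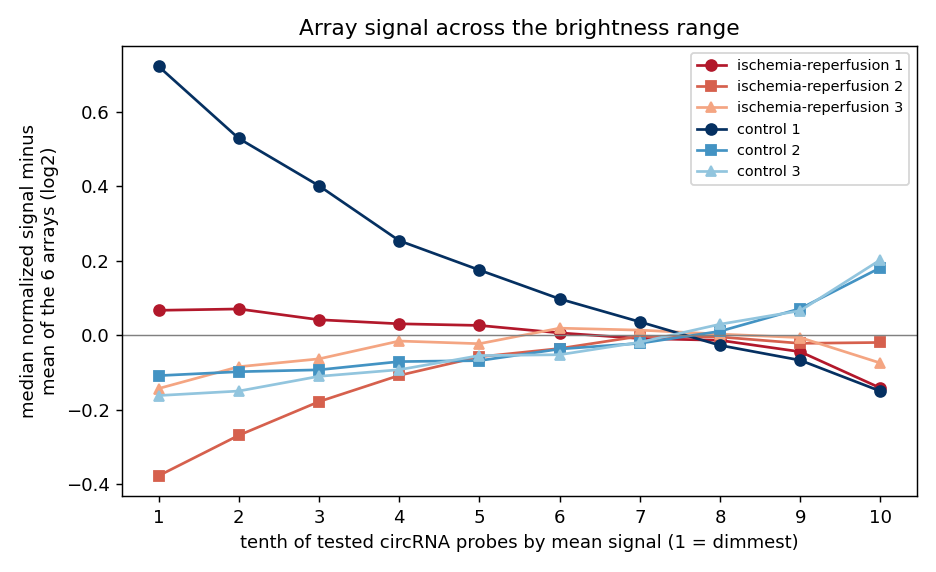
Median normalized log2 signal of each array, minus the mean of the 6 arrays, in 10 equal groups of the tested circRNA probes ordered by mean signal. Each line is 1 array. Control 1 lay above every other array in the dimmest group, and controls 2 and 3 lay above the other 4 arrays in the brightest group.

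The array also carried probes for mRNA, which allowed a second comparison of the same hearts. Whether linear RNA was removed before labelling is not given, so the signals of these probes need not follow mRNA levels in the tissue. Of 43 mRNA probes tested, 1 passed an adjusted p of 0.05. Map2, a microtubule-associated protein best known from neurons, fell by 0.70 on the log2 scale (SE 0.14, limma adjusted p = 0.0499), from -1.55 ± 0.06 in controls to -2.25 ± 0.07 after ischemia-reperfusion (SD, n = 3 each). All 3 ischemia-reperfusion values lay below all 3 control values. Cyp2e1, a cytochrome P450 that oxidizes ethanol and other small molecules, had -3.08 ± 0.09 after ischemia-reperfusion against -2.29 ± 0.28 (SD, n = 3 each), a difference of -0.79 that did not pass (SE 0.18, limma adjusted p = 0.0508). Its difference was -0.49 with quantile scaling, -0.59 with cyclic loess and -0.61 relative to circRNA probes of like brightness. It was -0.48 with the slide row as a block, which sets the ischemia-reperfusion arrays against control replicate 1 alone. Both probes were dim, with Map2 signals of 13.9 to 22.1 intensity units after ischemia-reperfusion and 25 to 31.4 in controls. The 10 adenoviral E1A control probes, which have no target in rat RNA, had median normalized log2 signals of -2.95, -3.07 and -3.43 on ischemia-reperfusion arrays 1 to 3 and -2.05, -2.84 and -2.90 on control arrays 1 to 3. Their difference was -0.56 with no overlap between the groups (two-sided exact permutation p = 0.1, the smallest possible), and -0.28 without control replicate 1. The 20 custom probes without a name had a difference of -0.47 (two-sided exact permutation p = 0.6), and 0.03 without control replicate 1. Without that array Map2 had -0.74 and Cyp2e1 -0.95. With the replicate block the differences were unchanged and neither passed (limma adjusted p = 0.0762 for both, against a range over the 20 alternatives of 0.00808 to 0.442 for Map2 and 0.0103 to 0.721 for Cyp2e1). The Map2 call was also lost with a similar difference under quantile scaling (-0.57), under scaling to the median (-0.66) and relative to circRNA probes of like brightness (-0.66), with limma adjusted p = 0.403, 0.13 and 0.274. With normexp the difference was -0.20 (limma adjusted p = 0.442), where the added offset of 50 intensity units exceeds the signals of this probe and shrinks any difference by construction. The call was lost without ischemia-reperfusion replicate 1 or 2 and without control replicate 2 or 3 (limma adjusted p = 0.25, 0.0580, 0.168 and 0.263), with differences of -0.66, -0.72, -0.69 and -0.68, close to that on all 6 arrays. In contrast, 5 probes passed without ischemia-reperfusion replicate 3 and 5 without control replicate 1, Map2 and Cyp2e1 among them each time.

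Members of the gene lists fixed beforehand were few on the array. Of the hypoxia and glycolysis list, 2 genes were measured and 0 passed. Ldha, which makes lactate from pyruvate, had log2 differences of -0.66 (SE 0.33) and -0.33 (SE 0.24) at its 2 probes, with limma adjusted p = 0.274 and 0.382. Leaving out 1 array moved these differences between -1.03 and -0.33 and between -0.46 and -0.12, and the first probe passed without ischemia-reperfusion replicate 3 (-1.03, limma adjusted p = 0.0360, range over the 20 alternatives 0.0360 to 0.521). The first probe was dim, at 9.07 to 40.9 intensity units over the 6 arrays, whereas the second read 692 to 2106. Pgk1, an ATP-producing enzyme of glycolysis, had a difference of -0.41 (SE 0.16, limma adjusted p = 0.189), with no overlap between the groups. Of the mitochondrial list, 1 gene was measured, Sdha, the flavoprotein subunit of succinate dehydrogenase, with a difference of -0.56 (SE 0.22, limma adjusted p = 0.189). Sdha passed without control replicate 1 (-0.78, limma adjusted p = 0.0316, the lowest over the 20 alternatives) and under array quality weights (-0.70, limma adjusted p = 0.0478). It did not pass under the other 18. Its difference was -0.13 with the slide row as a block, which sets the ischemia-reperfusion arrays against control replicate 1 alone. Of the ubiquitin ligase list, Trim2 had a difference of 0.00 (SE 0.23, limma adjusted p = 0.992). Of the inflammation and leukocyte list, Nlrp3, the sensor of an inflammasome, was detected on 2 of the 6 arrays and was not tested. The other 11 lists had 0 members among the mRNA probes.

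None of the remaining named mRNAs passed the test on all 6 arrays. Pdk3, a kinase that inhibits pyruvate dehydrogenase, had a log2 difference of -0.41 (SE 0.15), and Pop7, a subunit of ribonuclease P, one of -0.53 (SE 0.17). In both the groups did not overlap. The ribosomal protein genes Rplp1 and Rpl13a had -0.54 (SE 0.27) and -0.26 (SE 0.17), and the translation factor Eif4b had -0.35 (SE 0.20). Slc28a2, a nucleoside transporter, had -0.51 (SE 0.34). The chaperone Hsp90ab1 had -0.37 (SE 0.19), and Dlg4, a scaffold protein of synapses, had -0.25 (SE 0.17). Some of these depended on the scaling. With quantile scaling, with cyclic loess and relative to circRNAs of like brightness, Pdk3 had -0.13, -0.22 and -0.22, and Hsp90ab1 had -0.13, -0.08 and -0.18. Pop7 had -0.50, -0.52 and -0.55, close to its main value. Several of these mRNAs depended on single arrays. Rplp1 passed without ischemia-reperfusion replicate 3 (-0.85, limma adjusted p = 0.0360, range over the 20 alternatives 0.0360 to 0.591). Pop7 and Hsp90ab1 passed without control replicate 1 (-0.64 and -0.55, limma adjusted p = 0.0408 for both, with ranges of 0.0408 to 0.411 and 0.0408 to 0.974), and Pop7 also passed under array quality weights (-0.60, limma adjusted p = 0.0478). Without control replicate 1 the groups lay in different rows of the slide. With the slide row as a block, Pop7 had -0.29 and Hsp90ab1 -0.005. That fit compares with control replicate 1 alone, so both values rest on 1 control array. When 1 array was left out, the differences ranged from -0.85 to -0.34 for Rplp1, -0.35 to -0.15 for Rpl13a, -0.45 to -0.18 for Eif4b, -0.73 to -0.17 for Slc28a2, -0.55 to -0.27 for Hsp90ab1, -0.35 to -0.16 for Dlg4, -0.64 to -0.45 for Pop7 and -0.46 to -0.35 for Pdk3. Actb, cytoplasmic actin, had the largest positive difference among the named mRNAs, 0.38 (SE 0.18, limma adjusted p = 0.269), again with no overlap between the groups, and 0.25 to 0.52 when 1 array was left out. Differences smaller than their SE were seen for Ppp2r2b (-0.13), Med16 (-0.10), Hprt1 (-0.04), Ptk2b (-0.03), P2rx2 (-0.02), B2m (0.07), Ndfip1 (0.07), Cdh2 (0.15) and Pdcd10 (0.24), as for Trim2.

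In all, 19 of the 25 named probes, for 24 genes, had negative differences and 6 had positive ones, with a median of -0.26. With quantile scaling, with cyclic loess, and relative to circRNAs of like brightness, 15 were negative and 10 positive, and the probes that turned positive were among those with differences smaller than their SE. At an unadjusted limma p under 0.05 there were 9 of the 43 tested mRNA probes, where 2.15 were expected by chance. There were 4 with quantile scaling, 3 with scaling to the median, 4 with cyclic loess, 4 relative to circRNAs of like brightness, and 3 to 13 when 1 array was left out. The groups did not overlap for 6 of the 25 named probes, or 24.0%, where chance gives 10%. The naming rule left out the tested probes of Gusb, Fgf2 and Magoh, each detected on 5 of the 6 arrays. Their differences were -0.90 (SE 0.34), -0.37 (SE 0.24) and -0.04 (SE 0.38), with limma adjusted p = 0.189, 0.356 and 0.953. The Gusb difference was the largest of all tested mRNA probes.

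**Figure D2:**
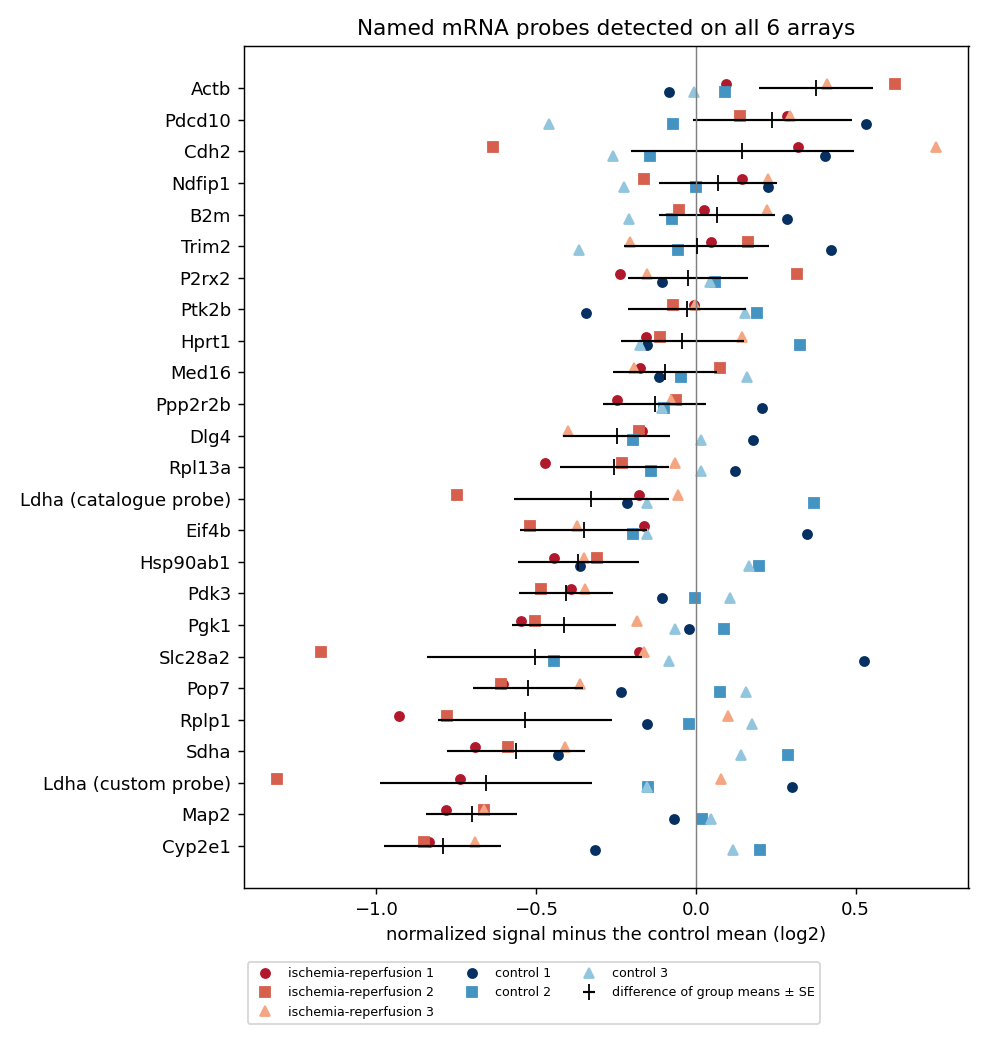
Normalized log2 signal minus the control mean for 25 mRNA probes detected on all 6 arrays. Colored points are single arrays, and black bars are the difference of group means ± SE from limma. The 3 ischemia-reperfusion values of Map2 and Cyp2e1 lay below all control values, and those of Actb lay above them.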

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

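Normexp on median intensity, cyclic loess, array quality weights, the slide row as a block, the brightest 25% of circRNAs and the comparison with circRNAs of like brightness were chosen after seeing the data. The planned slide block, the host gene alternatives and normexp on mean intensity were not run. A count of 0 circRNAs past the adjusted threshold was found under every alternative except 2. The replicate block gave 1 higher and 16 lower, and array quality weights 1444 and 1930. The cause was not tested for any change below unless one is given.

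Numbers at 1.5-fold with an unadjusted p under 0.05 (280 higher, 443 lower) moved by over 1.5 times as follows. Quantile scaling gave 517 higher and 208 lower, cyclic loess 572 and 235, normexp 93 and 64, normexp with quantile scaling 136 and 6 (its offset of 50 intensity units shrinks differences of dim probes by construction), the plain two-sample test 90 and 170, and array quality weights 899 and 941. Only the higher count moved with scaling to the median (452). Only the lower count moved in the deposited log2 table (22), with the replicate block (808) and in the brightest 25% (109, where fewer circRNAs were tested). The slide row as a block gave 29 higher and 2093 lower. By construction it sets the ischemia-reperfusion arrays against control replicate 1 alone, the only control in their row. Leaving out 1 array gave 96 to 945 higher and 188 to 867 lower. The named circRNAs with printed values kept their direction under all alternatives run but not their size. ASCRPR001910 ranged from -1.04 to -0.09 and ASCRPR008444 from -1.10 to -0.14, smallest with normexp and quantile scaling, while ASCRPR010701 ranged from 0.73 to 1.17 and ASCRPR002405 from 0.71 to 1.02. All 4 passed the adjusted threshold under array quality weights only.

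The number of mRNA probes past the adjusted threshold, 1, became 0 with quantile scaling, scaling to the median, normexp with either scaling, no filter on dim probes, the replicate block, cyclic loess, the slide row as a block, and relative to circRNAs of like brightness. It became 2 with the percentile over probes detected on all arrays, with only probes detected on all 6 arrays, and with the trend and robust options, and 4 with array quality weights. Leaving out 1 array gave 0 to 5. The replicate block changed no call on a named gene other than Map2.

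Signs of 10 genes with differences below their SE changed, never past the threshold. Quantile scaling gave Ppp2r2b 0.064, P2rx2 0.23, Ptk2b 0.26 and Hprt1 0.39, cyclic loess 0.029, 0.15, 0.13 and 0.29, and the comparison with circRNAs of like brightness 0.017, 0.13, 0.12 and 0.30, in that order. Normexp with quantile scaling gave 0.014, 0.047, 0.017 and 0.043 for the same genes, and normexp alone P2rx2 0.019, Hprt1 0.024 and Trim2 -0.012. Scaling to the median gave P2rx2 0.015 and Ptk2b 0.012, and the percentile over probes detected on all arrays Trim2 -0.0019. The slide row as a block gave Pdcd10 -0.29, Ndfip1 -0.16, P2rx2 0.083, Med16 0.017, Cdh2 -0.26, Ptk2b 0.32, Trim2 -0.42, B2m -0.22 and Hprt1 0.11. Leaving out 1 array gave ranges of -0.044 to 0.18 for Ndfip1, -0.20 to 0.083 for P2rx2, -0.16 to 0.54 for Cdh2, -0.20 to 0.068 for Ptk2b, -0.18 to 0.21 for Trim2, -0.039 to 0.21 for B2m and -0.13 to 0.12 for Hprt1. Over the printed circRNAs and named mRNA probes, 504 values under an alternative kept direction and side of the threshold, 17 newly passed it, 13 no longer passed it (all of Map2) and 47 changed sign. The number of detected circRNAs per array stayed within the spread between animals under all alternatives run. Dim probes limit the comparison, since 1178 circRNAs were not above background on all arrays of either group and were not tested.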

Other observations

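The tests on control replicate 1, on the share of lower circRNAs and on the balance of mRNA to circRNA were chosen after the result each bears on had been seen.

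Dim circRNA probes were brighter on control replicate 1 than on the other 5 arrays, by a median of 1.32 on the log2 scale in the dimmest 10% of all circRNA probes. Against a general brightness of the glass or an offset of the scanner, hairpin and empty spots rose by at most 0.668 background-subtracted intensity units, against 7.31 for the dimmest circRNA probes. A change of circRNA in that animal as the whole source is argued against by the adenoviral E1A control probes, for which rat RNA holds no target. Their median rise was 1.15, or 156% of that of circRNA probes of like brightness, and 7 of the 10 were brightest on that array, although 2 fell, by 0.30 and 0.21. The 20 custom probes without a name rose by a median of 1.48, and 15 of them were brightest on that array. Non-specific hybridization on that array is a candidate explanation that stays open. It would have to spare those 2 E1A probes and the 12 RC control probes, which lay at the level of empty spots and changed by -0.24 (0.610 background-subtracted units). An uneven amount of a spiked control RNA was not tested.

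More circRNAs were lower than higher at 1.5-fold with an unadjusted p under 0.05. Without control replicate 1 the share of lower circRNAs was 47.8%, against 61.3% with it, but the lower count rose from 443 to 867 and the higher count from 280 to 945, so this share does not settle whether its raised dim probes gave the excess. Of the 443 lower circRNAs, 262 still met both criteria without that array, against 157 to 324 without 1 of the others. All 443 stayed negative without it, with a median log2 difference of -0.72 against -0.71 with it. The median went from -0.75 to -0.64 for the 314 in the dimmer part and from -0.65 to -0.85 for the 129 in the brighter part. Since these circRNAs were chosen as lower over all 6 arrays, this does not decide the source either. With the tested circRNAs split at their median signal, the counts went from 52 higher and 314 lower to 369 and 185 in the dimmer part, and from 228 higher and 129 lower to 576 and 682 in the brighter part, so the majority turned round in both. The share also moved with other arrays, to 84.4% without ischemia-reperfusion replicate 1 and 51.6% without replicate 2 of that group, and to 77.4% and 82.7% without control replicates 2 and 3.

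Splits of the 6 arrays into 3 and 3 are too few, at 10, for a share under 0.05. The real split gave 723 circRNAs at 1.5-fold with an unadjusted p under 0.05, the highest other 917, and 3 of the 10 splits gave at least as many as the real one. All 10 splits gave 0 circRNAs past the adjusted threshold in the unblocked fit. For mRNA probes past it the real split gave 1, the highest other 1, and 2 of the 10 splits gave as many. At an unadjusted limma p under 0.05 the real split gave 9 mRNA probes and the other splits 0 to 5. The 2 splits above the real one, with 917 and 807 circRNAs, put both replicate 1 arrays in one group, but other splits that did so gave 611 and 543. Those with 917 and 807 also kept together control replicates 2 and 3, the second row of the slide, as the real one did. The split with 106 did so too. Among the 4 splits that part all 3 replicate pairs, the real one gave 723 and the others 213, 106 and 46. With the replicate block these gave 1188 against 410, 207 and 91, and 17 circRNAs past the adjusted threshold against 0 in each of the others. The pairs were accepted because deviations from the real group means correlated between same-numbered arrays in these same data. That choice can favour the real split in the blocked fit, and 4 splits are too few to decide.

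One hypothesis was that the groups part more clearly among bright circRNAs, where control replicate 1 is not raised. In the brightest 25% of tested circRNAs the real split gave 824 at an unadjusted limma p under 0.05, and 2 of the 10 splits gave as many, the other with 1037. That other split puts both replicate 1 arrays in one group, but splits that do so gave 1037, 678, 17 and 12. This alone therefore does not account for 1037. The splits with 1037 and 678 also keep together control replicates 2 and 3, the second row of the slide, as does the real one. So does the split with 41. The bound was set before these counts but after the raised dim probes of control replicate 1 were known. It took in every split, left out pairing and slide row, and was not met. Among the 4 splits that part all 3 pairs the real one gave 824 and the others 41, 30 and 7, and 4 splits are too few to decide. A second hypothesis was that circRNAs with consecutive probe numbers respond alike. Across 11922 neighbouring pairs the log2 differences, taken relative to circRNAs of like brightness, correlated at r = 0.0233, below the highest of 1000 random orders (0.0261), which it had to exceed by the bound set beforehand, but above most of them (permutation p = 0.005, one-sided), and it was left open. Another was that the balance of mRNA to circRNA signal differs between the groups. The median mRNA probe relative to circRNAs of like brightness was -0.15, -0.06 and 0.04 on ischemia-reperfusion arrays 1 to 3 and 0.00, 0.18 and 0.18 on control arrays 1 to 3, a difference of -0.179 (two-sided exact permutation p = 0.2, smallest possible 0.1). By replicate number the ischemia-reperfusion array was lower in 3 of 3 pairs, with differences of -0.152, -0.236 and -0.148 (two-sided exact sign-flip permutation p = 0.25, the smallest possible), and 3 pairs are too few to decide.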
